A study of Mus musculus with 18 samples.

How the data were processed

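RNA-seq was measured in thymic epithelial cells (TEC) sorted from Kat7 knockout (KO) and wildtype (WT) C57BL/6 mice, per the labels. The sorted subsets were cortical TEC (cTEC) and medullary TEC with high or low surface MHC class II (mTEChi and mTEClo). Per the labels, each of 3 WT pools of mice (numbered 1 to 3) and 3 KO pools (numbered 4 to 6) gave 1 library of each subset, so the 18 libraries made 6 groups of 3. Which exons of Kat7 were deleted, and in which cells, was not given in the sources used here. Nor were days of sorting or sequencing, so any difference of batch between WT and KO pools could not be separated from the genotype. The labels' protocols state that RNA was treated with DNase on the column, that cDNA was made and amplified with the SMART-Seq v4 low-input kit, that libraries were made by Nextera XT tagmentation, and that they were sequenced as 75 base paired ends on an Illumina NextSeq. These kits do not record the strand of a transcript, so reads from overlapping antisense genes could not be told apart, and reads from near-identical paralogs (such as the Dcpp, Ccl21, Tas2r, Hspa1 and Reg families) were taken as uncertain between family members.

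The values used were raw read counts per gene that the authors made with featureCounts on the mm10 mouse genome, per the submitters' processing notes. The deposited counts were whole numbers with no normalization, as the values themselves showed. The aligner, the featureCounts version and its settings for multimapping reads were not given in the sources used here. Each library had its own count file with a gene length and a symbol, and the counts in the table of the whole series were identical to those in the single files. Each file held 27179 genes under Entrez identifiers. Of these, 1312 had no symbol in the files and 35 of the 1312 were named from the RefSeq table of GRCm38.p6, the assembly that mm10 stands for. Gene coordinates were taken from that table. All genes entered the library totals, which ran from 3554089 to 20054360 counts.

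Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and the groups as given, which left 19364 genes. Library sizes were scaled by TMM. Group means were fitted for all 18 libraries together (12 residual degrees of freedom) and contrasts were tested with glmQLFit and glmQLFTest, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The adjusted p-values of single genes below are from this test and have 3 libraries per group. Levels are CPM, that is counts scaled to TMM-adjusted library sizes, as mean ± SD of the 3 libraries, and log2 fold changes are the fitted coefficients with SE derived from the test. Contrasts were KO against WT in each subset, pairs of subsets within the WT and mTEChi against mTEClo within the KO, and the differences of the KO effect between subsets (interactions). The KO and WT samples came from different mice and were not paired.

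Gene lists were fixed before the data were examined, together with the tests, the alternatives and the rule for named genes. There were 48 lists with 887 genes (885 matched, 6 of them through a synonym) that covered TEC identity, presentation, rare medullary cell types that resemble other tissues, antigens of other organs, cell types that a thymic sort can carry over, and signs of the cell cycle and RNA quality. Lists of organ antigens were also pooled into 1 list. Lists were tested with camera in limma 3.58.1 on the edgeR fit with a preset inter-gene correlation of 0.01 and adjustment over all lists within a contrast. The call of a list was repeated with the correlation estimated per list, and that adjusted p is given where it ended a call, unless stated otherwise. Members were counted after adjustment over all genes and again adjusted over the list alone. Named genes were Kat7 and Aire, then for KO against WT the 8 most raised and 8 most lowered genes among those with adjusted p below 0.05, libraries of the groups not overlapping and a mean of at least 5 CPM, leaving out predicted and sex-linked genes, and up to 4 members per list with the smallest adjusted p. For subset contrasts and interactions these were 5, 5 and up to 3. The text gives a selection of these, and some genes that the rule named are not reported here.

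The number of genes detected was taken at equal depth, as genes with 5 or more reads after thinning every library to the smallest total, as the mean of 10 seeded draws, and compared by a two-sided exact permutation test, which with 3 against 3 libraries cannot go below p = 0.1. Where a group had 0 reads of a gene, a fold was given only as a bound against a floor of 3 reads over the group's libraries, and list medians of pairs of groups were repeated with such genes at that bound, the second value being given where it differed. The libraries were amplified and carried no molecular identifiers, so floors cover counting error only, and the spread between pools was taken as the error of every comparison. In pairs of replicates the chi-square of the counts per degree of freedom was 3.43 to 47.2, so no pair was 1 library deposited under several names.

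Because the pool numbers in the labels mark the mice that gave all 3 subsets, they pair the libraries across subsets. Deviations from the group means correlated at 0 to 0.24 (median 0.06) across genes for libraries of the same pool and at -0.18 to 0.06 (median -0.03) for libraries of other pools. Deviations from a mean of 3 libraries sum to 0, so the values for other pools largely follow from those of the same pool. The pairing given by the labels was used as an alternative for the subset and interaction contrasts, with the pool as a block (8 residual degrees of freedom).

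The scripts were tested on simulated data made from the real means and library sizes, with 200 genes changed among 19159 tested. For KO against WT in mTEChi, 73% of the genes changed 2-fold and 94% of those changed 4-fold were recovered, in mTEClo 85% and 99%, and in cTEC 86% and 99%. Among unchanged genes 17, 4 and 7 were called in these contrasts, 0 changed genes had the wrong sign, and a list shifted on purpose was called with 0 other lists. The changed genes had a mean of at least 5 CPM and lay outside the lists, so the recovered shares hold only for such genes. Genes were simulated independently of each other, so the test cannot show how often lists of correlated genes are called falsely.

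The alternatives tried were RLE scaling and library-size scaling without TMM, DESeq2 1.42.0, limma-voom with quality weights, limma-voom with the pool as a random effect, no filter on low counts, a filter of 5 CPM in 3 libraries, fits with only the compared groups, a fold of at least 2, leaving out each library in turn, camera with estimated correlations, and fry. For breadth they were no thinning and minimums of 1 and 10 reads. A further 2 alternatives were chosen after the data were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.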

Results

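RNA-seq libraries were made from thymic epithelial cells, the stromal cells that select developing T cells, of wildtype (WT) mice and of mice labelled as Kat7 knockout (KO). Cortical cells (cTEC) support positive selection, and medullary cells (mTEC) display antigens of other organs to thymocytes. The mTEC were split by surface MHC class II into a high fraction (mTEChi), which holds the mature cells that express the autoimmune regulator Aire, and a low fraction (mTEClo), which holds immature cells and several rare cell types. Each of the 6 groups had 3 libraries from separate pools of mice. Library totals were 3554089 to 8445355 counts in WT mTEChi and 6802970 to 13373646 in KO mTEChi. In mTEClo they were 6565309 to 9815559 in WT and 14411708 to 19356071 in KO, and in cTEC 13300969 to 18338441 in WT and 15822957 to 20054360 in KO. The KO libraries of mTEC were thus the deeper ones on average. Among 19364 genes tested, the first principal component (55.7% of the variance) placed WT mTEChi at 172.5 to 178.9, KO mTEChi at 91.5 to 100.8 and all mTEClo and cTEC libraries lower. The second (14%) separated WT cTEC (-64.3 to -41) from KO cTEC (74.4 to 77.8).

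The targeted gene was lower in every KO library. Kat7 (Entrez 217127, chromosome 11, 95271853 to 95310246 on GRCm38.p6) encodes a histone lysine acetyltransferase of the MYST family. It was measured at 38.6 to 83.4 CPM in the 9 WT libraries and at 0.765 to 4.16 CPM in the 9 KO libraries. In mTEChi the level was 54.2 ± 5.72 CPM in WT and 2.33 ± 0.753 CPM in KO (log2 fold change -4.47, SE 0.29, adjusted p = 7.52e-09). In mTEClo it was 46.5 ± 9.94 and 1.23 ± 0.642 CPM (-5.28, SE 0.29, adjusted p = 1.81e-10), and in cTEC 72.2 ± 13.2 and 3.22 ± 0.95 CPM (-4.50, SE 0.26, adjusted p = 8.42e-11). Of 9 genes of the KAT7 complexes, 1 rose and 0 fell in mTEChi, Kat7 not being among the 9, and the list was not called in mTEChi (camera adjusted p = 0.543), mTEClo (0.585) or cTEC (0.885).

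The comparison of KO with WT mTEChi asked what loss of Kat7 changed in the mature medullary cells that carry out promiscuous expression of tissue antigens. Transcripts of organ antigens fell broadly in KO mTEChi. Reg3g, a lectin of the intestine, went from 2710 ± 592 to 217 ± 26.5 CPM (log2 fold change -3.64, SE 0.29, adjusted p = 4.08e-08). Csn2, which encodes the milk protein beta-casein, went from 930 ± 90.1 to 231 ± 17.3 CPM (-2.01, SE 0.24, adjusted p = 4e-06). Ins2, which encodes insulin, went from 25.9 ± 1.21 to 3.48 ± 1.59 CPM (adjusted p = 0.000112). Gp2 of pancreatic zymogen granules, which was also on the list of microfold cell mimics, went from 558 ± 62.8 to 89.4 ± 20.7 CPM (adjusted p = 1.44e-06). Pomc, the precursor of pituitary hormones, went from 144 ± 6.92 to 25.1 ± 3.08 CPM (adjusted p = 1.48e-05). Aire itself was at 1180 ± 75.7 CPM in WT and 677 ± 38 CPM in KO, a log2 fold change of -0.81 (SE 0.31) whose adjusted p rounded to 0.05 and lay just under the threshold. That error was shared over all 6 groups. The mTEChi libraries themselves lay at 1100 to 1230 CPM in WT and at 633 to 703 CPM in KO.

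Over the 330 antigen genes tested from all organ lists, 172 fell and 12 rose (190 and 12 adjusted over the list alone), the median log2 fold change was -1.56 and camera gave an adjusted p of 3.23e-12, which held with an estimated correlation (0.0106). All 11 tested antigens that earlier reports had found to depend on AIRE fell (11 adjusted over the list alone, median -2.38, camera adjusted p = 1.53e-06). Of 4 antigens reported as independent of AIRE 1 rose and 0 fell (camera adjusted p = 0.867), and of 9 reported to depend on FEZF2 3 rose and 3 fell (camera adjusted p = 0.771). By organ, antigens of salivary, lacrimal, nasal and prostate tissue fell in 25 of 29 members (26 adjusted over the list alone, camera adjusted p = 4.32e-09). Those of stomach and intestine fell in 28 of 39 with 2 higher (30 and 2 adjusted over the list alone, 4.28e-08), and those of pancreas in 16 of 27 with 1 higher (19 and 1 adjusted over the list alone, 6.98e-06). These organ lists and the AIRE-dependent list also held with an estimated correlation. The lists of liver, ovary and mammary, brain, muscle and heart, skin, and kidney and lung were called lower as well (13 to 17 members each, 14 to 19 adjusted over the list alone, camera adjusted p = 0.000356 to 0.00144), but these calls were lost at adjusted p = 0.0632 to adjusted p = 0.145 with an estimated correlation. Testis antigens, of which 1 of 24 fell, were not called (0.141), nor were those of the eye (0.0676). A few antigens rose, among them Zp2, a protein of the egg coat, from 153 ± 13.7 to 541 ± 36 CPM (adjusted p = 1.2e-05).

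Genes of tuft cells, a chemosensory cell type with medullary mimics, rose in KO mTEChi. Of 20 tested members 17 rose and 0 fell (17 and 0 adjusted over the list alone), with a median of 1.22 and a camera adjusted p of 1.1e-15, against adjusted p = 0.0925 with an estimated correlation. In WT, 19 of the 20 were lower in mTEChi than in mTEClo. Admixture of mTEClo-type cells in KO mTEChi was tested only for the antigens, so it stays open for the tuft genes. Alox5, an enzyme of leukotriene synthesis, went from 20.3 ± 4.69 to 129 ± 11.4 CPM (log2 fold change 2.68, SE 0.23, adjusted p = 9.08e-08). The cyclooxygenase gene Ptgs1 went from 30.7 ± 2.64 to 122 ± 12 CPM, and Plcb2, a phospholipase of taste signalling, from 35.9 ± 6.83 to 118 ± 18 CPM. The most raised genes included Chrna9, a nicotinic receptor subunit, from 7.93 ± 2.01 to 74.1 ± 7.94 CPM, the lens crystallin Cryba2 from 40.3 ± 2.56 to 336 ± 41.2 CPM, and Ovol3 from 8.81 ± 1.3 to 59.3 ± 16.8 CPM. The most lowered included Hdx (log2 fold change -5.00, SE 0.68), the gut hormone gene Gip (-4.27, SE 0.63), the myosin-binding protein gene Mybpc1 (-4.18, SE 0.31) and the odorant-binding Obp2a (-4.14, SE 0.44). Mimics of ciliated cells were lower in 13 of 17 members with 1 higher (13 and 1 adjusted over the list alone, camera adjusted p = 0.000164, and adjusted p = 0.0632 with an estimated correlation). They included the cell fate regulator Mcidas (24.7 ± 2.16 to 6.05 ± 1.04 CPM). Mimics of enterocytes and hepatocytes were lower in 15 of 19 with 1 higher (15 and 1 adjusted over the list alone, 1.17e-05, and adjusted p = 0.13 with an estimated correlation).

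Genes of the cortical identity list rose in 12 of 19 members and fell in 3 (13 and 5 adjusted over the list alone, median 0.53, camera adjusted p = 6.33e-05, and adjusted p = 0.222 with an estimated correlation). Among them Prss16, a thymus-specific protease, went from 48.8 ± 5.82 to 177 ± 25 CPM (adjusted p = 7.66e-06) and the chemokine gene Cxcl12 from 16.4 ± 1.21 to 66.9 ± 3.7 CPM (1.02e-08). Foxn1, the transcription factor that specifies thymic epithelium, went from 112 ± 16 to 286 ± 36 CPM (log2 fold change 1.36, SE 0.17, adjusted p = 7.83e-06), and the basal keratin gene Krt14 from 447 ± 34.3 to 1090 ± 102 CPM. The interferon response list rose in 12 of 20 members and fell in 2 (13 and 2 adjusted over the list alone, camera adjusted p = 0.000139, and adjusted p = 0.241 with an estimated correlation). In WT, 17 of these 20 members and Krt14 were lower in mTEChi than in mTEClo, so admixture of mTEClo-type cells stays open for them too. Ccl21a, a gene of immature mTEC, lay at 41.6 to 56 CPM in WT mTEChi and at 66.3 to 98.2 CPM in KO mTEChi. In KO mTEClo it lay at 303 to 692 CPM. These values limit the share of immature mTEC in KO mTEChi, but not that of other cells in the mTEClo fraction. The MHC class II list fell in 6 of 14 and rose in 1 (7 and 1 adjusted over the list alone, 0.00105, and adjusted p = 0.349 with an estimated correlation). H2-Ob, a modulator of peptide loading, went from 156 ± 8.15 to 37.6 ± 5.58 CPM (adjusted p = 6.17e-08) and H2-Aa from 7560 ± 328 to 5030 ± 138 CPM (adjusted p = 0.000873). The chemokine genes Ccl20 (455 ± 22.9 to 75.2 ± 14.2 CPM) and Ccl22 (179 ± 30.5 to 54.6 ± 9.59 CPM) also fell.

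By edgeR, 3305 genes were higher and 3741 lower in KO than in WT mTEChi, a balance that turned without a filter on low counts (3588 and 3462) and without WT mTEChi replicate 1 (2972 and 2964) or 2 (2872 and 2685) or KO mTEChi replicate 4 (2697 and 2619), 5 (3140 and 2875) or 6 (2945 and 2739). With a fold of at least 2 there were 654 higher and 2612 lower genes. Without WT mTEChi replicate 3 the lower count was 2436, and Aire passed the threshold in 7 of 14 alternatives (adjusted p = 4.91e-05 to 0.129). Markers of macrophages and dendritic cells were lower in 9 of 16 members and higher in 2 (9 and 3 adjusted over the list alone, camera adjusted p = 0.0687). Lyz2 was at 1450 ± 33.5 CPM in WT and 819 ± 61.5 CPM in KO. Of 20 thymocyte markers 2 rose and 4 fell (2 and 3 adjusted over the list alone, camera adjusted p = 0.842). Mitochondrial transcripts took 1.5 ± 0.176% of counts in WT and 1.15 ± 0.22% in KO, the ribosomal precursor Rn45s 0.563 ± 0.179% and 0.324 ± 0.0448%, and Lars2, 2 ± 0.235% and 1.4 ± 0.085%.

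**Figure D1:**
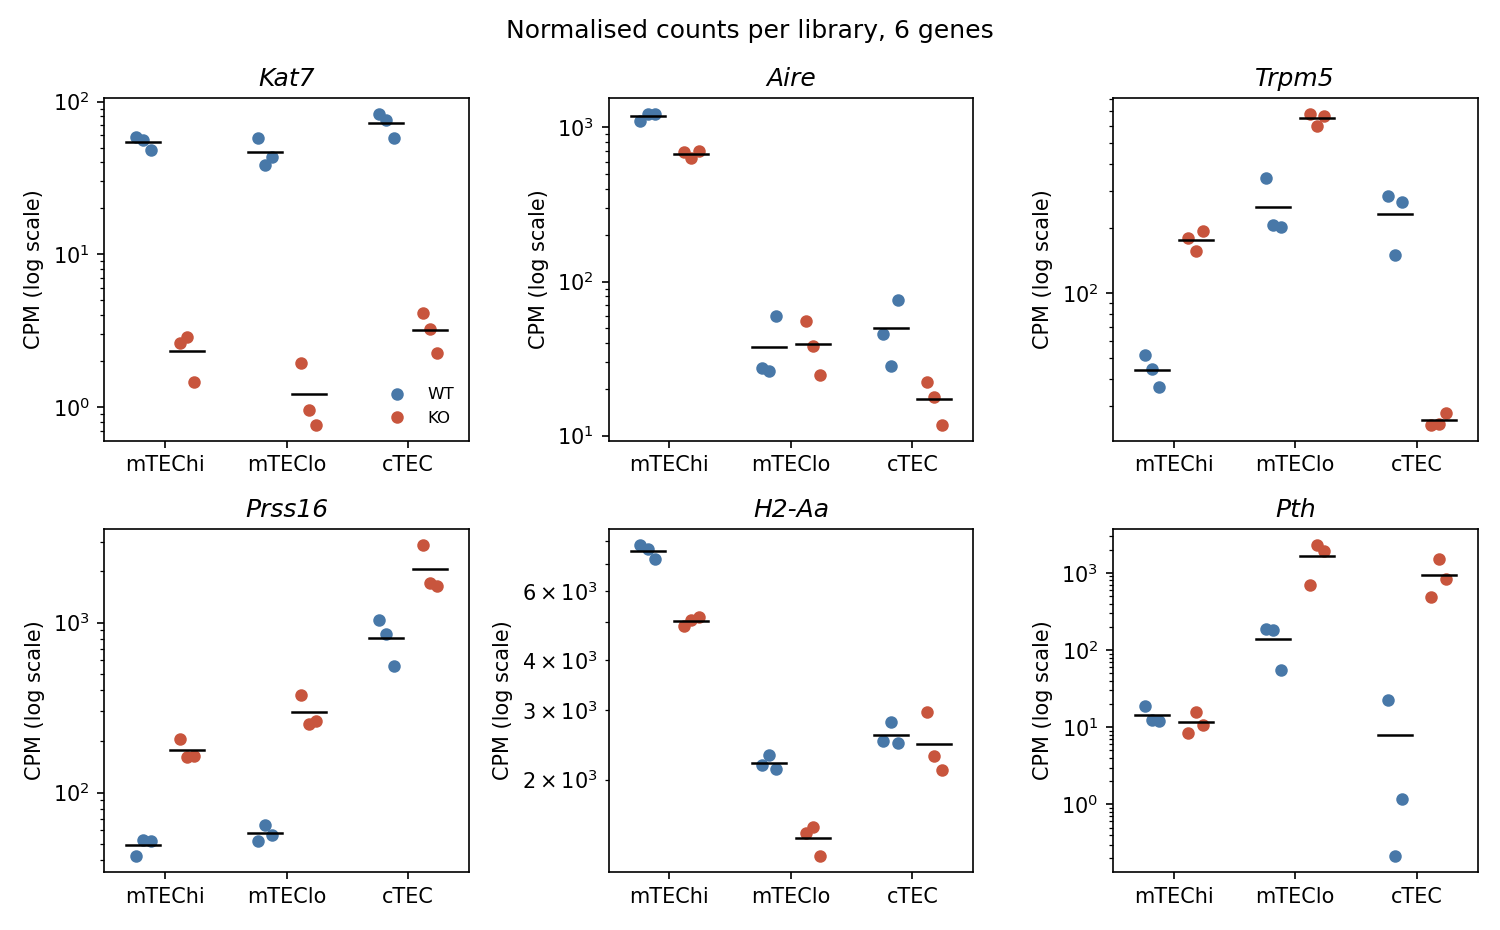
Level of 6 genes in each of the 18 libraries, in CPM on a log axis, with WT and KO libraries of mTEChi, mTEClo and cTEC side by side; points are libraries and bars mark the mean of 3. Kat7 lay between 38.6 and 83.4 CPM in WT and between 0.765 and 4.16 CPM in KO. The tuft cell channel gene Trpm5 was higher in KO mTEClo (651 against 251 CPM on average), and the parathyroid hormone gene Pth was higher in KO mTEClo and KO cTEC than in WT.

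In mTEClo, the comparison asked what loss of Kat7 changed in the fraction that holds mTEC progenitors and many of the rare mimetic cells. Genes of tuft cells rose here too, while the MHC class II list and several genes of immature mTEC that produce CCL21 fell. The calls of these 3 lists were lost with an estimated correlation (adjusted p = 0.424 for tuft genes, adjusted p = 0.285 for MHC class II and adjusted p = 0.285 for CCL21 mTEC), as were those of all lists called in mTEClo. Trpm5, the cation channel of tuft cell sensing, went from 251 ± 80.6 to 651 ± 43.4 CPM (log2 fold change 1.37, SE 0.21, adjusted p = 3.44e-05) and Sh2d7 from 80.1 ± 17.9 to 224 ± 6.45 CPM (adjusted p = 4.25e-06). Lifr, the receptor of leukemia inhibitory factor, went from 721 ± 28.2 to 123 ± 14.2 CPM (-2.55, SE 0.15, adjusted p = 3.21e-10). The eosinophil chemokine gene Ccl11 fell, with 863 ± 158 CPM in WT and 15.3 ± 3.83 CPM in KO (-5.82, SE 0.29, adjusted p = 3.9e-11).

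Of the 20 tuft genes 15 rose and 0 fell in KO mTEClo (15 and 0 adjusted over the list alone, median 0.99, camera adjusted p = 1.61e-05, and adjusted p = 0.424 with an estimated correlation). Of 17 neuroendocrine genes 7 rose and 1 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.0433, and adjusted p = 0.37 with an estimated correlation). That call was also lost without WT mTEClo replicate 2 (adjusted p = 0.131). In the group, Chga, which encodes a granin of secretory vesicles, went from 178 ± 40.6 to 1560 ± 457 CPM (log2 fold change 3.14, SE 0.43, adjusted p = 1.27e-05). Insm1, a neuroendocrine transcription factor, went from 20.2 ± 1.31 to 46.3 ± 1.74 CPM, whereas Scg2 was lower (46.4 ± 17.3 to 11 ± 0.814 CPM). The parathyroid hormone gene Pth went from 141 ± 74.1 to 1650 ± 849 CPM (adjusted p = 0.00111). Across the KO mTEClo libraries Chga followed Pth, at 1050, 1920 and 1730 CPM where Pth was at 692, 2310 and 1950 CPM. Whether both came from mimetic cells or from carried-over cells was not tested. The cortical identity list rose in 12 of 19 members and fell in 3 (12 and 4 adjusted over the list alone, median 1.00, camera adjusted p = 0.0089, and adjusted p = 0.477 with an estimated correlation). Prss16 went from 57.4 ± 6.05 to 297 ± 68.4 CPM, the T cell chemoattractant gene Ccl25 from 108 ± 10.8 to 363 ± 32.5 CPM and Foxn1 from 73 ± 14.7 to 192 ± 36 CPM. Il7, a survival factor of early T cells on the same list, fell from 393 ± 33.4 to 124 ± 2.2 CPM (adjusted p = 5.93e-09), while Kitl rose from 5.1 ± 0.944 to 27 ± 4.36 CPM.

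The MHC class II list fell in 11 of 14 members and rose in 1 (12 and 1 adjusted over the list alone, median -0.76, camera adjusted p = 5.03e-07, and adjusted p = 0.285 with an estimated correlation). H2-Ab1 was at 6770 ± 545 CPM in WT and 4120 ± 488 CPM in KO. The list fell in both KO fractions, which were themselves sorted on surface MHC class II. Lower expression and a shift of cells across the gate cannot be told apart in these fractions. In KO cTEC, which were not split into high and low MHC class II, the list was called lower too (camera adjusted p = 0.0489). That call was lost without WT cTEC replicate 2 (adjusted p = 0.15) or KO cTEC replicate 5 (0.0634) or 6 (0.107). It was also lost with an estimated correlation (value not reported here). The inhibitory ligand genes Pdcd1lg2 (42 ± 7.94 to 6.35 ± 0.741 CPM, log2 fold change -2.73, SE 0.19) and Cd274 (137 ± 13.6 to 73.2 ± 10.4 CPM) fell. The thymic chemokine list fell in 8 of 15 and rose in 2 (8 and 2 adjusted over the list alone, 0.00527, and adjusted p = 0.285 with an estimated correlation). Within it Ccl20 went from 237 ± 47.5 to 16.3 ± 3.77 CPM. The CCL21 mTEC list fell in 5 of 13 and rose in 2 (5 and 2 adjusted over the list alone, 0.00772, and adjusted p = 0.285 with an estimated correlation). The interferon response list fell in 10 of 20 (10 adjusted over the list alone, 0.0019, and adjusted p = 0.404 with an estimated correlation). The combined antigen list, with 66 of 330 lower and 42 higher (65 and 40 adjusted over the list alone), was not called (0.114). Of the 11 AIRE-dependent antigens 5 fell (5 adjusted over the list alone, 0.0089, and adjusted p = 0.285 with an estimated correlation). Aire was at 37.6 CPM in WT and 39.3 CPM in KO (log2 fold change 0.07, SE 0.33, adjusted p = 0.897). The most raised genes included Ogn, a small proteoglycan (0.411 ± 0.37 to 21.6 ± 1.9 CPM), and Cnmd, which encodes chondromodulin (3.59 ± 1.46 to 159 ± 13.2 CPM, log2 fold change 5.42, SE 0.21, adjusted p = 1.88e-12). The most lowered included Slitrk4 (21.4 ± 3.09 to 0.128 ± 0.136 CPM) and Nkain4 (45.3 ± 8.58 to 0.563 ± 0.336 CPM).

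In all, 3657 genes were higher and 3056 lower in KO mTEClo. The balance turned with RLE scaling (3256 higher and 3374 lower), with DESeq2 (3388 and 3519) and with only the compared groups fitted (3594 and 3744), and with a fold of at least 2 there were 1163 and 1614. Signs of RNA quality moved with the genotype here. The list of immediate early and dissociation genes fell in 8 of 20 members (9 adjusted over the list alone, camera adjusted p = 0.0019, and adjusted p = 0.557 with an estimated correlation), with Hspa1a at 2710 ± 125 and 1070 ± 72.7 CPM. Mitochondrial transcripts took 2.48 ± 0.487% of counts in WT and 1.51 ± 0.146% in KO, the ribosomal precursor Rn45s 1.11 ± 0.129% and 0.359 ± 0.0571%, and Lars2 3.04 ± 0.681% and 1.23 ± 0.213%. Markers of mural cells fell in 4 of 8 members (4 adjusted over the list alone, 1.61e-05, and adjusted p = 0.2 with an estimated correlation). Tagln was at 395 ± 50.6 and 50.7 ± 5.23 CPM and Rgs5 at 85.5 ± 4.45 and 11.1 ± 0.866 CPM. Nuclear-encoded genes of oxidative phosphorylation rose in 8 of 19 members (10 adjusted over the list alone, 0.0152, and adjusted p = 0.321 with an estimated correlation).

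**Figure D2:**
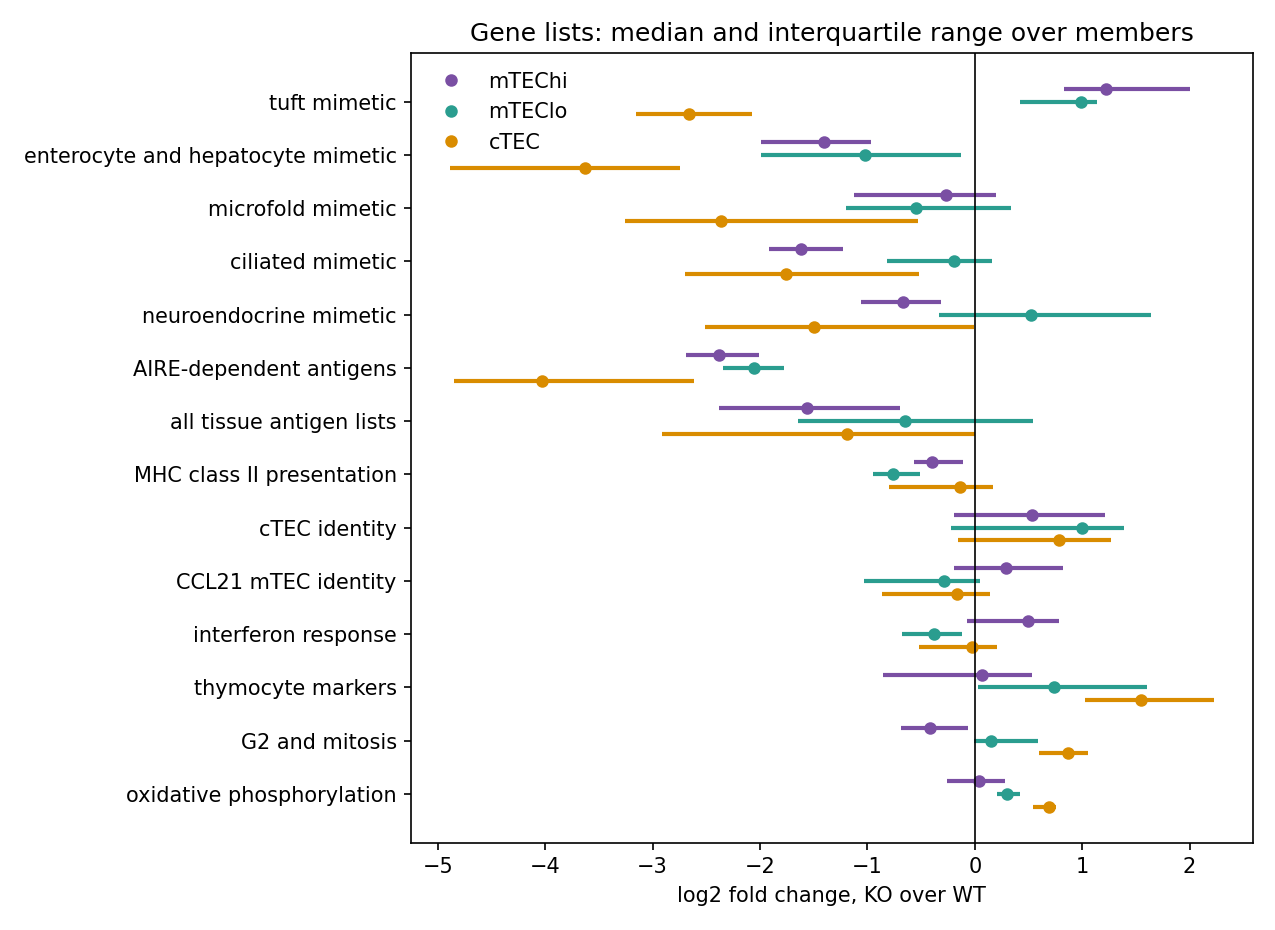
Median log2 fold change of KO against WT for 14 gene lists in mTEChi, mTEClo and cTEC, with lines spanning the middle part of each list from the 25% to the 75% quantile. The tuft list had medians of 1.22 in mTEChi, 0.99 in mTEClo and -2.66 in cTEC, and the combined antigen list -1.56, -0.65 and -1.19, of which the last values became -0.56 and -0.92 with genes at 0 reads at their bound.

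In cTEC, the comparison asked what loss of Kat7 changed in the cortical cells. Transcripts typical of medullary mimetic cells, which the WT cTEC libraries also held, fell, and genes of thymocytes and of cell division rose. The enterocyte, hepatocyte and microfold calls held with an estimated correlation, but other calls were lost at adjusted p = 0.0693 for tuft genes, adjusted p = 0.251 for thymocytes, adjusted p = 0.353 for G2 and mitosis and adjusted p = 0.127 for DNA replication with an estimated correlation. Gnat3, the gustatory G protein subunit of tuft cells, went from 286 ± 32.8 to 32.3 ± 4.84 CPM (log2 fold change -3.15, SE 0.17, adjusted p = 2.73e-11). Reg3g went from 2000 ± 501 to 74.4 ± 20.8 CPM (-4.75, SE 0.31, adjusted p = 2.79e-10). The cortical genes Enpep (102 ± 21.4 to 307 ± 24.4 CPM, 1.60, SE 0.14), Cxcl12 (667 ± 110 to 1350 ± 165 CPM) and Foxn1 (120 ± 17.1 to 307 ± 45 CPM, adjusted p = 1.9e-06) rose. Ccl21a, a gene of immature mTEC, lay at 638 to 942 CPM in WT cTEC and at 111 to 356 CPM in KO cTEC. A smaller share of mTEClo-type cells in KO cTEC was not tested, and it cannot be told apart from a rise of cortical genes.

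All 20 tuft genes fell in KO cTEC (20 adjusted over the list alone), with a median of -2.66 and a camera adjusted p of 3.65e-27, against adjusted p = 0.0693 with an estimated correlation. The WT cTEC level of the tuft genes was a median of 306% of that in WT mTEChi. The enterocyte and hepatocyte list fell in 18 of 19 members (18 adjusted over the list alone, median -3.63, 3.93e-17). The microfold list fell in 8 of 12 with 2 higher (10 and 2 adjusted over the list alone, 3.24e-10) and the stomach and intestine antigens in 24 of 39 (24 adjusted over the list alone, 4.32e-06). These 3 lists held with an estimated correlation (0.0463, 0.0463 and 0.0488). Examples were Cdhr5, a brush border cadherin (51.9 ± 21.2 to 1.49 ± 0.338 CPM), Cdx1, an intestinal homeobox gene (52.1 ± 13.8 to 8.18 ± 1.03 CPM), and Spib, a transcription factor of microfold cells (276 ± 77.3 to 35.9 ± 11 CPM). The combined antigen list fell in 138 of 330 members and rose in 24 (138 and 24 adjusted over the list alone, median -1.19, or -0.92 with genes at 0 reads at their bound, 0.00113, and adjusted p = 0.188 with an estimated correlation). The mature mTEC list fell in 11 of 18 and rose in 1 (11 and 1 adjusted over the list alone, 0.000229, and adjusted p = 0.113 with an estimated correlation). Aire was at 49.8 ± 24.1 CPM in WT and 17.3 ± 5.38 CPM in KO cTEC (log2 fold change -1.53, SE 0.34, adjusted p = 0.000895). The neuroendocrine list fell in 10 of 17 and rose in 2 (10 and 2 adjusted over the list alone, 0.0362, and adjusted p = 0.254 with an estimated correlation). Its member Chga, however, went from 39.9 ± 27.7 to 818 ± 505 CPM (4.37, SE 0.46, adjusted p = 2.05e-07), and Pth, outside that list, from 7.93 ± 12.6 to 943 ± 526 CPM (6.99, SE 0.92, adjusted p = 3.59e-06). Across the KO cTEC libraries Chga followed Pth, at 351, 1350 and 748 CPM where Pth was at 483, 1520 and 831 CPM. Whether both came from mimetic cells or from carried-over cells was not tested here either.

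Genes of the cortical identity list rose in 11 of 19 members and fell in 4 (12 and 5 adjusted over the list alone, median 0.78, camera adjusted p = 0.0112, and adjusted p = 0.401 with an estimated correlation). The oxidative phosphorylation list rose in 16 of 19 (16 adjusted over the list alone, median 0.69, 5.7e-05, and adjusted p = 0.113 with an estimated correlation). Sdhb, a subunit of complex II, went from 162 ± 8.38 to 284 ± 32.1 CPM. The list of G2 and mitosis rose in 16 of 22 (17 adjusted over the list alone, 0.000229, and adjusted p = 0.353 with an estimated correlation). That of DNA replication rose in 13 of 26 (13 adjusted over the list alone, 0.000946, and adjusted p = 0.127 with an estimated correlation). Rrm1, a subunit of ribonucleotide reductase, was at 49.8 ± 22.7 and 213 ± 31.8 CPM. Thymocyte markers rose beside these groups in 14 of 20 members (16 adjusted over the list alone, median 1.55, 1.84e-05, and adjusted p = 0.251 with an estimated correlation). Cd8b1 was at 7.51 ± 4.25 and 48.6 ± 16.2 CPM, Cd8a at 9.74 ± 4.47 and 44.4 ± 14.2 CPM and the pan-leukocyte gene Ptprc at 9.51 ± 2.18 and 29 ± 7.32 CPM. The chemokine gene Ccl20 (452 ± 81.1 to 16 ± 9.07 CPM), Tnfrsf11b, which encodes the RANKL decoy receptor osteoprotegerin (137 ± 24.2 to 10.2 ± 2.52 CPM), and Pdcd1lg2 (39 ± 9.87 to 2.25 ± 0.379 CPM) fell. The list of immediate early and dissociation genes fell in 12 of 20 and rose in 1 (12 and 1 adjusted over the list alone, 0.0168, and adjusted p = 0.471 with an estimated correlation). This call was also lost without KO cTEC replicate 4 (adjusted p = 0.0867). Mural cell markers fell in 4 of 8 and rose in 1 (4 and 2 adjusted over the list alone, 0.0267, and adjusted p = 0.222 with an estimated correlation), a call also lost without WT cTEC replicate 2 (adjusted p = 0.0631). The most raised genes included Cnmd (8.18 ± 1.38 to 395 ± 54.9 CPM, log2 fold change 5.59, SE 0.19, adjusted p = 1.55e-13). The most lowered included Ccl11 (381 ± 123 to 3.37 ± 0.358 CPM, -6.82, SE 0.32) and Lyz1, a lysozyme gene of Paneth cells (603 ± 452 to 9.18 ± 6.46 CPM).

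By edgeR, 4321 genes were higher and 5166 lower in KO cTEC, or 4939 and 4888 by limma-voom with the pool as a random effect and 1085 and 3385 with a fold of at least 2. Replicates of WT cTEC differed more among themselves than those of the other groups, with a chi-square per degree of freedom of 26.2 between replicates 1 and 2, 47.2 between 1 and 3 and 44.5 between 2 and 3. Mitochondrial transcripts took 1.53 ± 0.406% of counts in WT cTEC and 1.65 ± 0.129% in KO cTEC, Rn45s 0.495 ± 0.159% and 0.378 ± 0.0551%, and Lars2 1.73 ± 0.382% and 1.39 ± 0.138%.

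The breadth of expression was compared because mature mTEC transcribe an unusually large part of the genome. At equal depth, WT mTEChi had 17674.4 ± 135.3 genes with 5 or more reads and KO mTEChi 15874.6 ± 23.1, a difference of -1799.8 genes. In cTEC the values were 15141.4 ± 132.6 in WT and 14197.5 ± 98.4 in KO (-944), and in mTEClo 15328.3 ± 156.9 and 14998.9 ± 53.3 (-329.4). The KO and WT libraries did not overlap in any subset, and the two-sided exact permutation p was 0.1 in each, the smallest that 3 against 3 libraries can give. They overlapped in cTEC when 1 read was enough and in mTEChi without thinning (exact permutation p = 0.3 in both). Without thinning, the deeper KO mTEClo libraries had 882 more genes than the WT ones, so the direction in mTEClo rested on equal depth.

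**Figure D3:**
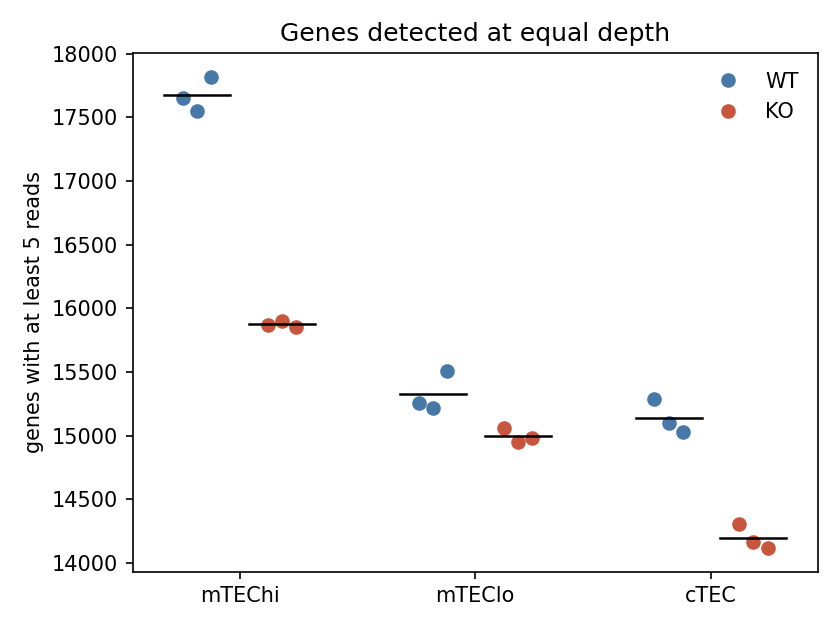
Number of genes with at least 5 reads in each library after all libraries were thinned to the same total, with the vertical axis starting above 0; points are libraries and lines are the means of 3. KO mTEChi averaged 15874.6 genes and WT mTEChi 17674.4, while both mTEClo and cTEC groups lay at 14197.5 to 15328.3 on average.

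The WT subsets were compared with each other to give the background against which KO effects were read. In WT mTEChi against WT mTEClo, the costimulatory receptor gene Cd40 was at 464 ± 2.13 and 73.6 ± 7.48 CPM and Cd80 at 71.6 ± 3.97 and 7.78 ± 0.356 CPM (log2 fold change 3.20, SE 0.17, adjusted p = 1.61e-11). Csn2 was at 930 ± 90.1 and 48.6 ± 8.13 CPM. Ccl21a, which encodes a chemokine that draws thymocytes into the medulla, was lower in mTEChi (48.4 ± 7.2 against 1550 ± 26.3 CPM), as were Krt14 (447 ± 34.3 against 1720 ± 113 CPM) and Gnat3 (97.3 ± 10.8 against 741 ± 202 CPM). The mature mTEC list was higher in 16 of 18 members (16 adjusted over the list alone, camera adjusted p = 9.37e-13) and the combined antigens in 250 of 330 with 15 lower (254 and 16 adjusted over the list alone, 2.29e-13). Costimulation was higher in 9 of 11 (10 adjusted over the list alone, 1.38e-09), and the CCL21 mTEC list was lower in 11 of 13 (11 adjusted over the list alone, 1.89e-14). These held with an estimated correlation, as did G2 and mitosis, higher in 22 of 22 (22 adjusted over the list alone, 2.61e-15), and the interferon list, lower in 17 of 20 with 1 higher (17 and 1 adjusted over the list alone, 1.67e-15). The tuft list was lower in 19 of 20 (19 adjusted over the list alone, 1.81e-15, and adjusted p = 0.0547 with an estimated correlation). Several genes had 0 reads in WT mTEClo, and against a floor of 3 reads over its libraries Slamf1 was at least 111-fold and the mast cell protease genes Cma1 and Mcpt4 at least 110-fold and 93.2-fold higher in WT mTEChi. Markers of macrophages and dendritic cells, higher in 15 of 16 with 1 lower (15 and 1 adjusted over the list alone, 3.54e-07), moved with these groups, with Lyz2 at 1450 ± 33.5 and 119 ± 10.3 CPM. Mural cell markers were lower in 3 of 8 with 1 higher (3 and 1 adjusted over the list alone, 0.00617, and adjusted p = 0.102 with an estimated correlation). The dissociation list was lower in 18 of 20 (18 adjusted over the list alone, 3.22e-08, and adjusted p = 0.16 with an estimated correlation). In all 6306 genes were higher and 5172 lower in WT mTEChi.

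Against WT cTEC, WT mTEChi had lower Cxcl12 (16.4 ± 1.21 against 667 ± 110 CPM, log2 fold change -5.35, SE 0.15), Pax1 (35.4 ± 2.77 against 314 ± 12 CPM) and Ackr4, a scavenging chemokine receptor gene (5.26 ± 1.52 against 166 ± 17.1 CPM). Ctsl, the cathepsin of cortical peptide processing, was lower as well (247 ± 48 against 2950 ± 837 CPM), and Icosl was higher (455 ± 45.9 against 31.5 ± 1.91 CPM). The cortical identity list was lower in 12 of 19 with 2 higher (12 and 2 adjusted over the list alone, camera adjusted p = 1.88e-11). The combined antigens were higher in 263 of 330 with 12 lower (263 and 12 adjusted over the list alone, 9.56e-14) and the mature mTEC list in 16 of 18 (16 adjusted over the list alone, 7.24e-12). All 3 held with an estimated correlation. Prr9, with 0 reads in WT cTEC, was at least 363-fold higher in WT mTEChi. Markers of macrophages and dendritic cells moved with these groups, higher in 14 of 16 with 1 lower (14 and 1 adjusted over the list alone, 1.6e-05, held with an estimated correlation at 0.029), for instance Lyz2 (1450 ± 33.5 against 152 ± 43 CPM) and Fcer1g (51.3 ± 1.45 against 3.22 ± 0.559 CPM). B cell markers were higher in 7 of 9 with 1 lower (8 and 1 adjusted over the list alone, 0.0318, and adjusted p = 0.12 with an estimated correlation), and that call was also lost with the pool as a block (adjusted p = 0.0541). Mural cell markers were lower in 4 of 8 with 1 higher (4 and 1 adjusted over the list alone, 0.0418, and adjusted p = 0.197 with an estimated correlation), a call also lost without WT cTEC replicate 2 (adjusted p = 0.056) or WT mTEChi replicate 3 (adjusted p = 0.0507). The dissociation list was lower in 18 of 20 (18 adjusted over the list alone, 4.82e-11, and adjusted p = 0.108 with an estimated correlation). In this contrast 6960 genes were higher and 5517 lower.

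WT mTEClo and WT cTEC differed in fewer genes, with 2518 higher and 2797 lower in mTEClo. The higher count was 1663 by limma-voom with quality weights and 1161 with only the compared groups fitted, while with the pool as a random effect 3299 were higher and 2806 lower. Enpep (4.57 ± 0.152 against 102 ± 21.4 CPM, log2 fold change -4.47, SE 0.18, adjusted p = 3.08e-12) and Pax1 (100 ± 18.2 against 314 ± 12 CPM) were lower in mTEClo. So were Cxcl12 (129 ± 11.1 against 667 ± 110 CPM) and Ccl25 (108 ± 10.8 against 818 ± 224 CPM), and the synaptic vesicle gene Snap25 (21.4 ± 4.08 against 4.78 ± 0.82 CPM) was higher. The cortical identity list was lower in 16 of 19 with 1 higher (16 and 1 adjusted over the list alone, camera adjusted p = 3.82e-38), which held with an estimated correlation (0.00495). The neuroendocrine list was higher in 8 of 17 (10 adjusted over the list alone, 1.19e-05, and adjusted p = 0.124 with an estimated correlation). The tuft list was higher in 11 of 20 (13 adjusted over the list alone, 1.53e-06, and adjusted p = 0.487 with an estimated correlation). Markers of other cells moved with this contrast, thymocyte markers being lower in mTEClo in 13 of 20 members (15 adjusted over the list alone, 4.15e-05, and adjusted p = 0.487 with an estimated correlation). Fibroblast markers were lower in 7 of 12 (8 adjusted over the list alone, 0.00031, and adjusted p = 0.296 with an estimated correlation). The dissociation list was lower in 10 of 20 (10 adjusted over the list alone, 0.000822, and adjusted p = 0.544 with an estimated correlation).

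Within the KO, mTEChi and mTEClo still differed in 8778 genes, with 4445 higher and 4333 lower in mTEChi. The balance turned with library-size scaling (4328 and 4666), with the strict filter (3521 and 3689) and with the pool as a block (4396 and 4632). With a fold of at least 2 there were 3378 higher and 1757 lower genes. Cd40 was at 324 ± 9.47 CPM in KO mTEChi and 50.3 ± 11.5 CPM in KO mTEClo, and Icosl at 459 ± 17.3 and 84.5 ± 11.6 CPM. Ccl22 was at 54.6 ± 9.59 and 1.49 ± 0.73 CPM (log2 fold change 5.24, SE 0.30), and Csn2 at 231 ± 17.3 and 10.8 ± 2.9 CPM (4.42, SE 0.27, adjusted p = 1.65e-10). The secreted proteins Igfbp3 (16.7 ± 2.94 against 259 ± 31.1 CPM) and Apoe (217 ± 14.6 against 1590 ± 37.1 CPM) were lower in KO mTEChi. So were the endocrine genes Chga (45.1 ± 14.1 against 1560 ± 457 CPM) and Pth (11.7 ± 3.82 against 1650 ± 849 CPM). The mature mTEC list was higher in 16 of 18 (17 adjusted over the list alone, camera adjusted p = 6.25e-22) and costimulation in 10 of 11 (10 adjusted over the list alone, 1.1e-16). MHC class II was higher in 12 of 14 with 2 lower (12 and 2 adjusted over the list alone, 3.79e-16) and the combined antigens in 179 of 330 with 19 lower (184 and 19 adjusted over the list alone, 9.1e-10). These 4 calls also held with an estimated correlation. The fractions were sorted on surface MHC class II, so the direction of that list was largely set by the sort. Markers of macrophages and dendritic cells were higher in 11 of 16 members (13 adjusted over the list alone, 1.48e-08), with Lyz2 at 819 ± 61.5 and 96.5 ± 12.1 CPM and Aif1 at 54.7 ± 17.9 and 7.3 ± 0.586 CPM. B cell markers were higher in 5 of 9 (6 adjusted over the list alone, 0.00835), and both of these lists held with an estimated correlation. The dissociation list was lower in 19 of 20 (19 adjusted over the list alone, 1.5e-06, and adjusted p = 0.197 with an estimated correlation), with Egr1 at 420 ± 86.4 and 1250 ± 168 CPM. The tuft list was lower in 19 of 20 (19 adjusted over the list alone, 2.26e-15, and adjusted p = 0.0615 with an estimated correlation).

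Genes enriched in WT mTEChi over WT mTEClo were followed in the KO. Of 6306 such genes, 2351 (37.3%) were called lower in KO mTEChi, against 1218.3 (19.3%) if the lists were independent and 10.6% of the 13058 genes not enriched. Among 3415 genes enriched at least 4-fold the share was 45.7%. Both contrasts share the WT mTEChi libraries, and in 20 simulations of unchanged groups against those libraries the correlation of the fold changes across genes was -0.107 (observed -0.564) and their covariance -0.095 (observed -1.214). With the list taken from 1 WT pool and the KO effect measured against the other WT pools, the shares were 35.9%, 31.3% and 31.3%, against 14.4%, 13% and 11.7% for independent lists. The share was 25.4% without WT mTEChi replicate 3, against 12.4% for independent lists.

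The KO effect itself differed between subsets. Between mTEChi and mTEClo it differed in 2610 genes (1300 relatively higher and 1310 relatively lower in mTEChi), against 4226 by limma-voom with quality weights, 4118 with only the compared groups fitted and 1629 with a difference of at least 2-fold. The interferon list was relatively higher in mTEChi in 12 of 20 members (15 adjusted over the list alone, median difference 0.85, camera adjusted p = 5.4e-14) and the CCL21 mTEC list in 10 of 13 with 2 lower (10 and 2 adjusted over the list alone, 0.99, 4.72e-07). Mural cell markers were relatively higher in 5 of 8 (5 adjusted over the list alone, 1.16, 1.09e-07), and the neuroendocrine list was relatively lower in 7 of 17 (9 adjusted over the list alone, -1.16, 3.08e-06). These 4 held with an estimated correlation. The dissociation list was relatively higher in 3 of 20 members (3 adjusted over the list alone, 0.0168, and adjusted p = 0.669 with an estimated correlation). That call was also lost without WT mTEClo replicate 1 (adjusted p = 0.0903), WT mTEChi replicate 2 (0.0671), KO mTEClo replicate 4 (0.0716) or KO mTEChi replicate 6 (0.142). Lifr (difference 2.03, SE 0.21, adjusted p = 2.22e-06) and the interferon gene Ddx58 (1.34, SE 0.14, 3.86e-06) were relatively higher in mTEChi, and Igfbp3 (-4.03, SE 0.29, 3.33e-08) and Chga (-3.65, SE 0.60, 0.000324) relatively lower. The combined antigens were relatively lower in mTEChi in 44 of 330 with 4 higher (44 and 4 adjusted over the list alone, 0.00225, and adjusted p = 0.213 with an estimated correlation).

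Between mTEChi and cTEC the KO effect differed in 6098 genes, or in 3671 with a difference of at least 2-fold. All 20 tuft genes were relatively higher in mTEChi (20 adjusted over the list alone, median difference 4.12, camera adjusted p = 7.31e-61, held with an estimated correlation at 0.0125). Among them were Trpm5 (5.20, SE 0.31, adjusted p = 4.44e-10) and Gnat3 (4.37, SE 0.23, 9.85e-11). Mural cell markers were relatively higher in 5 of 8 (5 adjusted over the list alone with 1 lower, 0.0253, and adjusted p = 0.371 with an estimated correlation), a call also lost without WT cTEC replicate 2 (adjusted p = 0.0642). Pth (-7.21, SE 1.22, 0.000158) and Chga (-4.88, SE 0.61, 5.38e-06) were relatively lower. So were G2 and mitosis genes in 16 of 22 members (19 adjusted over the list alone, 5.05e-07, and adjusted p = 0.371 with an estimated correlation) and thymocyte markers in 12 of 20 with 1 higher (14 and 1 adjusted over the list alone, 9.02e-05, and adjusted p = 0.448 with an estimated correlation). Between mTEClo and cTEC it differed in 5034 genes, or in 2973 with a difference of at least 2-fold. All 20 tuft genes were relatively higher in mTEClo (20 adjusted over the list alone, median difference 3.34, 1.01e-59, held with an estimated correlation at 0.0128). The enterocyte and hepatocyte list was relatively higher in 15 of 19 (17 adjusted over the list alone, 2.62, 5.91e-14, and adjusted p = 0.05 with an estimated correlation) and the neuroendocrine list in 9 of 17 (12 adjusted over the list alone, 1.70, 3.13e-05, and adjusted p = 0.0718 with an estimated correlation). DNA replication genes were relatively lower in 10 of 26 (11 adjusted over the list alone, 1.96e-05, and adjusted p = 0.0718 with an estimated correlation). Thymocyte markers were relatively lower beside them in 7 of 20 members with 1 higher (7 and 1 adjusted over the list alone, 0.0109, and adjusted p = 0.513 with an estimated correlation), with differences of -2.55 (SE 0.50) for Cd3g and -2.61 (SE 0.57) for Cd3d, a call lost without WT cTEC replicate 3 (adjusted p = 0.0548). Fibroblast markers were relatively higher in 7 of 12 with 1 lower (8 and 1 adjusted over the list alone, 0.0258, and adjusted p = 0.466 with an estimated correlation). That call was lost without WT mTEClo replicate 1 (adjusted p = 0.073) or WT cTEC replicate 2 (adjusted p = 0.091). Endothelial markers were relatively higher in 3 of 9 (3 adjusted over the list alone, 0.0339, and adjusted p = 0.466 with an estimated correlation). That call was lost with the pool as a block (adjusted p = 0.14) and without WT cTEC replicate 2 (0.165), WT mTEClo replicate 2 (0.0552) or 3 (0.167), KO cTEC replicate 4 (0.0549) or 6 (0.0647), or KO mTEClo replicate 4 (0.0674) or 6 (0.0746). Lower calls made up 36.8% of this contrast with TMM and 24.4% with library-size scaling alone.

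Genes changed in more than 1 subset were counted against the number that independent lists would share. Higher in both mTEChi and mTEClo were 1768 genes (624.2 for independent lists) and lower in both 1296 (590.4). For mTEChi and cTEC these were 1403 (737.5) and 1691 (998), and for mTEClo and cTEC 1770 (816) and 1833 (815.3). In all 3 subsets 968 genes were higher (139.3 for independent lists) and 891 lower (157.5), Foxn1 and Cnmd being among the higher and Kat7, H2-Ob and Ccl20 among the lower. Across genes, which are not independent replicates, the KO effects correlated at 0.399, 0.378 and 0.444 in these pairs, with covariances of 0.493, 0.602 and 0.776, and the libraries compared were distinct but came from the same pools of mice.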

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

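The tests of mTEChi-type cells in cTEC, of mTEClo-type cells among mTEChi, of unequal depth and of thymocyte RNA were chosen only after the results they concern were seen. The differences of the KO effect between subsets were picked out because the interaction term passed its threshold. Between mTEChi and mTEClo this held for 2610 genes (4226 by limma-voom with quality weights and 4118 with only the compared groups fitted), of which 382 were called in opposite directions in the 2 subsets (188 higher and 194 lower in mTEChi), for the interferon list (median difference 0.85) and for the neuroendocrine list (-1.16). Between mTEChi and cTEC it held for 6098 genes, 938 of them called in opposite directions, and for the tuft list (median difference 4.12). Between mTEClo and cTEC it held for 5034 genes, 674 of them called in opposite directions, and for the tuft (3.34) and neuroendocrine (1.70) lists.

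Tuft and tissue antigen transcripts were lower in KO than in WT cTEC, while tuft transcripts were higher in KO mTEChi and mTEClo, list calls that were all lost with an estimated correlation (adjusted p = 0.0693 and 0.188 in cTEC, 0.0925 in mTEChi and 0.424 in mTEClo). A WT cTEC library apart from the others was tested by leaving each out, and 20 of the 20 tuft genes were still called lower without any 1 of them. A smaller admixture of mTEChi-type cells in the KO libraries would need tuft transcripts in WT cTEC to be as low against WT mTEChi as Aire was (4.21%), but they stood a median of 6.17 log2 units above that ratio (19 genes, middle part 5.64 to 6.53), which argues against it for the tuft genes. For the antigens the same difference was 1.33 over 217 genes with a middle part of -0.40 to 3.02, so admixture and lower expression in the cortical cells cannot be told apart, because Aire and the antigens need not share the same cells. Admixture of cells richer in tuft than in Aire transcripts was not tested and stays open beside an effect of the genotype, so fewer such cells in KO cTEC could account for the tuft genes.

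Tissue antigen transcripts were lower in KO mTEChi, beside a smaller difference in Aire. If mTEClo-type cells had diluted the KO mTEChi by 1 share, antigens scarce in mTEClo would have fallen by 1 common factor, but over 171 such antigens the squared deviations of the log2 fold changes from a common value averaged 4.01 times their squared errors (middle part of the fold changes -2.72 to -1.29), which argues against dilution as the whole cause. After removal of a trend with gene length the median over 330 antigens was -1.28, which argues against gene length as the whole cause. After thinning to the smallest total the median over 260 antigens was -1.59, but the KO libraries were the deeper ones on average, so thinning could hardly have removed the pattern and decides nothing. A change within mature mTEC and a different mix of mature stages among KO mTEChi both stay open, and lower antigen transcription after loss of Kat7 may be put forward only as a hypothesis.

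Thymocyte transcripts were higher in KO cTEC. All of the 20 members (100%) had a log2 fold change above 0 (middle part 1.03 to 2.23), but 14 of them had already been called higher, so this outcome was largely fixed by the pattern itself and decides nothing. Thymocytes or their RNA in the KO cTEC libraries and a change in the cortical cells themselves cannot be told apart, because no value here separates them, and no biological explanation was tested. The list call itself was lost with an estimated correlation (adjusted p = 0.251).

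Each comparison had 10 splits of its samples, so a share under 0.05 was out of reach. For the KO effects whole pools were regrouped. The real split called 7046 genes in mTEChi, 6713 in mTEClo and 9487 in cTEC by edgeR, and the highest other split 0, 0 and 1, so that 1 of 10 splits, the real one, gave as many. For the interactions the real split called 2610, 6098 and 5034 genes and the highest other 0, 1 and 0 (1 of 10 splits as large in each). In lists the real split called 20, 19 and 24 for the KO effects and 19, 13 and 20 for the interactions, and the highest other 19, 17, 20, 14, 8 and 20, with 1 split as large in each except 2 for mTEClo against cTEC. For mTEChi against mTEClo, mTEChi against cTEC and mTEClo against cTEC in WT and for mTEChi against mTEClo in KO the 6 libraries were regrouped, with 11478, 12477, 5315 and 8778 genes in the real split and at most 0, 0, 3 and 0 in the others (1 split as large in each), and with 28, 31, 10 and 31 lists against 32, 32, 14 and 32 (4, 2, 6 and 3 splits as large). Of those 10 splits 4 part the libraries of every pool, as the real one does, and the other 6 keep both libraries of a pool on 1 side. Calls of lists at the preset correlation were thus nearly as many, or more, in some splits that mixed the groups. Every mixed split kept 2 pools or libraries of 1 group together, so part of any real difference remained in it. The mixing also raised the spread, so few genes could be called. False list calls and that remaining difference cannot be told apart, which limits what the number of lists called can show.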

How the results depend on the processing

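The 2 alternatives that left out other-cell genes or medullary genes in cTEC were chosen only after the results were seen. Of 463 recomputed counts and values over 37 results, 417 kept their direction and stayed within the limits set for them, 31 were weaker, 9 stronger, 5 moved and 1 reversed. For single named genes, 11494 of the values left after removing 1 library were the same as before, 428 lost and 47 gained their call and 1 reversed, and under the other alternatives 13168 were the same, 149 lost and 132 gained it. The reversed one was the somatostatin gene Sst in the difference of the KO effect between mTEClo and cTEC, at -5.34 with all libraries, at -6.07 without WT cTEC replicate 1 and at 1.91 (adjusted p = 0.507) without KO cTEC replicate 6. Library-size scaling shifted the median of all genes by -0.115 in KO against WT cTEC and by 0.122 in the difference between mTEClo and cTEC, so fold changes in cTEC are relative to that shift.

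A fold of at least 2 left 654 higher genes beside 2612 lower ones in mTEChi, 1163 higher and 1614 lower in mTEClo, and 1085 higher and 3385 lower in cTEC. In WT mTEChi it left 4778 higher and 2397 lower genes against mTEClo, and 5127 higher and 2842 lower against cTEC. In KO mTEChi against mTEClo it left 3378 higher and 1757 lower, and in WT mTEClo against cTEC 934 and 1067. For the interactions it left 1629, 3671 and 2973 genes, and for overlaps 258 higher and 772 lower in both mTEChi and mTEClo, 121 higher in both mTEChi and cTEC, and 328 higher and 1024 lower in both mTEClo and cTEC. These are smaller because fewer genes change 2-fold. With limma-voom and quality weights and with only the compared groups fitted, WT mTEClo against cTEC had 1663 and 1161 higher genes and the interaction of mTEChi and mTEClo 4226 and 4118 genes (the cause was not tested).

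With estimated correlations 5, 0 and 3 lists were called for the KO effect in mTEChi, mTEClo and cTEC, 19 and 1 for WT mTEChi and mTEClo against cTEC, 18 within the KO, and 4, 1 and 1 for the interactions, while fry, which tests each list without comparing it with other genes, called 31, 29 and 43 for the KO effects, 44 for WT mTEChi against mTEClo, 27 for WT mTEClo against cTEC, and 32 and 36 for the interactions with cTEC. Lower calls made up 54.5% in cTEC with TMM and 63.6% with library-size scaling. The KO minus WT number of genes detected in mTEChi was -1552.5 with at least 10 reads and -930.3 without thinning, in mTEClo -496.4 with 1 read and 882 without thinning, and in cTEC -631 and -783.7 (the cause was not tested). Without genes higher in WT mTEChi than in WT cTEC, 3289 genes were lower in KO cTEC, as 1877 genes were left out by construction (36.3% of the lower genes, against 35.9% of all genes tested), and 2809 genes were higher under the same restriction. By contrast 4146 were higher without WT cTEC replicate 3 and without other-cell genes.

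Leaving out 1 library gave 2394 to 3140 higher and 2436 (without WT mTEChi replicate 3) to 2964 lower genes in mTEChi, 2761 to 3624 and 2346 to 2862 in mTEClo, and 3680 to 4395 and 4443 to 5192 in cTEC. With the pool as a block, WT mTEChi against mTEClo had 6467 higher and 5275 lower genes and the interactions 3112, 6636 and 5654. No count moved by over 1.5 times under this pairing. Among named genes and lists 3 genes and 8 lists lost their call, of which the report describes only the B cell markers in WT mTEChi against cTEC (adjusted p = 0.0541) and the endothelial markers in the interaction of mTEClo and cTEC (adjusted p = 0.14), and 12 genes and 6 lists gained one.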

Other observations

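Gcm2, Casr and the levels of Pth per library were looked at only after Pth was seen among the most raised genes, and the values are given without an explanation. Pth lay at 22.4, 0.212 and 1.17 CPM in the WT cTEC libraries and at 483, 1520 and 831 CPM in those of KO, and at 187, 180 and 55.5 CPM in WT mTEClo against 692, 2310 and 1950 CPM in KO. In mTEChi the libraries were at 11.9 to 18.8 CPM in WT and at 8.49 to 15.9 CPM in KO. Gcm2, which encodes a transcription factor of the parathyroid, had log2 fold changes of 4.62 (SE 0.88, adjusted p = 0.000237) in cTEC, 3.07 (SE 0.73, adjusted p = 0.00257) in mTEClo and -2.29 (SE 0.85, adjusted p = 0.0407) in mTEChi. Its reads were 6, 0 and 0 in WT cTEC against 24, 54 and 87 in KO. In mTEClo they were 18, 4 and 1 against 56, 139 and 220, and in mTEChi 10, 12 and 23 against 1, 9 and 4. The sizes of these fold changes thus rest on few reads. Casr, which encodes the calcium-sensing receptor, had one of -1.47 in cTEC (SE 0.34, adjusted p = 0.00121).

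Markers of other cells that the report has not described moved as follows in KO cTEC. Of 9 B cell markers 5 fell (6 adjusted over the list alone, camera adjusted p = 0.0697), of 12 fibroblast markers 7 fell and 1 rose (9 and 1 adjusted over the list alone, 0.125) and of 6 erythroid markers 5 fell (6 adjusted over the list alone, 0.125), so none of these lists was called by camera. Among the genes, Col3a1 went from 156 ± 99.2 to 12.1 ± 0.505 CPM, Fbn1 from 46.4 ± 10.4 to 9.35 ± 2.43 CPM, and Dcn, a proteoglycan gene, from 612 ± 96.3 to 2050 ± 97.9 CPM. Of 18 p53 targets 9 rose and 1 fell in mTEClo (9 and 1 adjusted over the list alone, 0.059), and Perp, a p53 target of epithelial adhesion, was higher in KO mTEChi (370 ± 29.4 to 950 ± 16.8 CPM), mTEClo (663 ± 47.2 to 1270 ± 51.3 CPM) and cTEC (668 ± 88 to 1500 ± 85.5 CPM). Pmaip1, a p53 target that promotes cell death, was lower in KO cTEC (114 ± 27.2 to 10.1 ± 2.76 CPM). The Y-linked Ddx3y lay at 109 to 139 CPM and Xist at 2.37 to 16.6 CPM in the group means, so every group held cells of male mice.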
